A study of Rattus norvegicus with 30 samples.

How the data were processed

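Total RNA of primary cultured rat inner medullary collecting duct cells was hybridised to 30 arrays, 1 array per sample. The platform was the Affymetrix Rat Gene 1.0 ST array, per the comment line of the probe table. The labels' protocols give a column-based RNA extraction and a whole-transcript labelling kit, which primes along the transcript instead of at its 3' end.

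The deposited values are on the log2 scale and were made by the authors with robust multi-array average (RMA), per the submitters' processing notes. RMA subtracts background, scales the arrays to each other and summarises the probes of a probe set into 1 value. Its version, software, background model and summary level are not given in the sources used here. The table held 29170 probe sets with no missing value. Array medians lay between 5.63 and 5.76 and upper quartiles between 7.60 and 7.83, so the distributions of the arrays were close but not identical. Array values flatten at the low and high ends of the scale, and the highest value in the table was 13.88, so changes of the brightest and dimmest genes can be understated and differences between changes can be understated or inflated. No spot-level intensity, background or scan batch was used here.

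Probe sets were named through the platform annotation. Of the 29170 probe sets, 15310 had 1 gene symbol, 323 had several and 13537 had no gene listed. The Entrez identifiers of 15279 of the 15310 single-symbol probe sets were matched to a gene table of the GRCr8 assembly, and 0 of them carried another symbol there. Each gene was represented by its probe set with the highest mean over the 30 arrays, which gave 14506 genes, 527 of them with more than 1 single-symbol probe set. Probe sets with several symbols were not used for named genes, which left Hspa1a, Hspa1b and Hspa1l unmeasured. The betaine transporter gene Slc6a12, Pnpla6 and Ranbp3l had no probe set named in the annotation used here. No genome position is given, since the build behind the array annotation is not stated.

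Samples were grouped by their titles into 10 groups of 3. Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit with 1 mean per group over all 30 arrays and eBayes, so that the groups shared an estimate of the spread of each gene. P-values were adjusted by the Benjamini-Hochberg method over the 14506 genes and judged at 0.05, and genes changed at least 2-fold were counted separately. Values are given as log2 change ± standard error (SE) of the fit or as group mean ± SD, with n = 3 arrays per group unless stated. With 3 arrays per group, the number of arrays limits the precision. The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The last 3 groups carry the replicate numbers 1, 2 and 9, the others 1, 2 and 3.

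The design, the gene lists, the rule for named genes and all alternatives but cyclic loess were fixed before the data were examined. In the main comparisons the rule named the largest increases and decreases without overlap between the replicates of the groups (5 each, or 3 each for the times after the step from 300 to 600). It also named the members with the smallest adjusted p of the tonicity, chaperone and collecting duct lists and of the other lists with the smallest list p. Nfat5, Akr1b1, Slc5a3, Slc6a6, Slc14a2 and Aqp2 were always named. In secondary comparisons the rule named the 3 largest increases and decreases, and symbols that start with LOC, RGD or MGC were left out.

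There were 16 functional lists: tonicity-responsive and organic osmolyte genes, heat shock proteins and co-chaperones, collecting duct principal cell genes, ion transport and cell volume genes, amino acid transporters, proliferation genes, p53 target and growth arrest genes, unfolded protein response genes, cholesterol synthesis and uptake genes, cytokine and NF-kB target genes, interferon-stimulated genes, immediate early genes, antioxidant and glutathione genes, glycolysis and hypoxia-inducible genes, oxidative phosphorylation genes, and matricellular genes responsive to TGF-beta or YAP. A further 6 lists held markers of epithelial cells, intercalated cells, fibroblasts and interstitial cells, loop of Henle and proximal tubule cells, endothelial cells and leukocytes. Of the 14 tonicity genes 10 were measured, and 4 of these also stood in another list. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 22 lists within a comparison. Of 374 tests 168 passed, and 73 of these also passed with the correlation estimated from the residuals. Every list that passed had a median, a mean and a test of the same sign.

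Alternatives were quantile normalization, median centring of each array, a filter on dim genes at the 30th percentile, the mean of a gene's probe sets, array weights, eBayes with trend and robust settings, only the compared arrays in the fit, the replicate number as a block, all arrays numbered 3 or 9 left out, each array left out in turn, all probe sets, and for lists an estimated correlation and the rotation test fry. Cyclic loess normalization was added after the data were seen. The fit was tested on simulated data with each gene's mean over the 30 arrays and its SD from the fit over all groups. In the comparison of 600 with 300 mosmol/kg, 200 of 14506 genes were changed. The simulated spread was normal and equal in all groups. In the arrays the median SD of a gene ran from 0.0751 in steady 300 to 0.155 at 3 h after the step from 300 to 600. It recovered 13 of 50 genes changed 1.25-fold, 45 of 50 changed 1.5-fold and 50 of 50 changed 2-fold, and it called 12 of 14306 unchanged genes.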

Results

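Primary cells of the rat inner medullary collecting duct were cultured in media of different osmolality and profiled on 30 expression arrays. In this duct vasopressin sets water reabsorption. In 3 groups the medium stayed at 300, 600 or 900 mosmol/kg, and these are called steady 300, steady 600 and steady 900. In 4 groups cells from 300 mosmol/kg were challenged with 600 mosmol/kg for 3, 12, 24 or 48 h. In 2 groups cells from 600 mosmol/kg were challenged with 900 mosmol/kg for 12 or 24 h, and in 1 group cells from 900 mosmol/kg were returned to 300 mosmol/kg for 24 h. Each group had 3 arrays. The treatment field of every sample names 5 µM cyclosporin A, an inhibitor of calcineurin, while no title mentions it, so the labels do not settle which cultures received it. Comparisons between groups assume that all cultures were treated alike.

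Replicates resembled each other closely, with correlations of 0.991 to 0.998 within groups, and the lowest correlation between any 2 arrays was 0.940. Each of the 30 arrays had its nearest neighbour in its own group, and no pair of arrays held identical values. The SD of a gene estimated by the fit for all groups together had a median of 0.131 on the log2 scale. By group, the median SD of a gene ran from 0.0751 in steady 300 to 0.155 at 3 h after the step from 300 to 600. Of 14506 genes, 10687 differed among the 10 groups by limma's moderated F test. The first principal component held 46.95% of the variance and ordered the steady cultures by osmolality, with mean scores of −36.7 in steady 300, 13.5 in steady 600 and 45.5 in steady 900. The cells at 48 h after the step from 300 to 600 had a mean score of −19.5. The cells returned from 900 to 300 had a mean score of 30.6, on this component nearer to steady 900 than to steady 300.

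**Figure D1:**
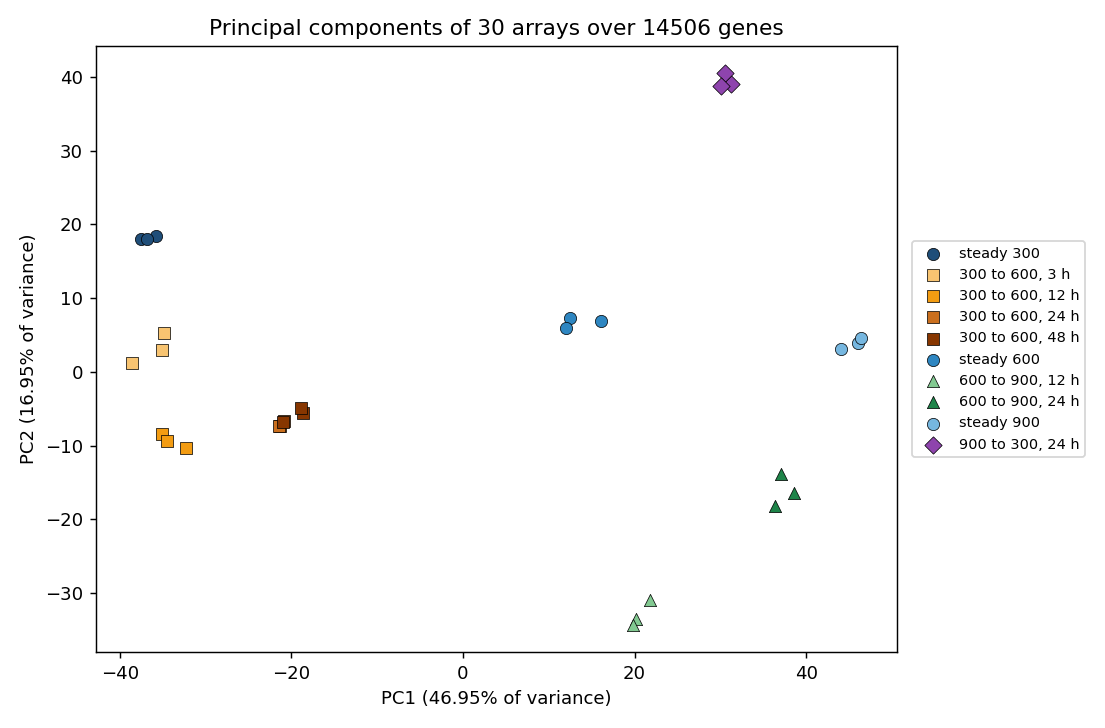
Scores of the 30 arrays on the first and second principal components (horizontal and vertical axes, arbitrary units, 46.95% and 16.95% of the variance) over 14506 genes, with colour and shape giving the group. The arrays of a group lie together, and steady 300, steady 600 and steady 900 follow each other along the horizontal axis.

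To describe cells adapted to a higher osmolality, steady 600 was compared with steady 300. Genes of collecting duct principal cells and of the interferon response were higher at 600 mosmol/kg, while cytokine genes and leukocyte markers were lower. Aqp2, the vasopressin-regulated water channel, rose from 5.61 ± 0.49 to 10.07 ± 0.48 (mean ± SD of log2 values, n = 3), a log2 change of 4.47 ± 0.20 (SE) or 22.1-fold. Slc14a2, which encodes the urea transporters of the collecting duct, rose 14.7-fold and the vasopressin receptor gene Avpr2 7.83-fold. The chemokine gene Cxcl6 was 74.5-fold lower, and the cytokine gene Il1a 36.8-fold lower.

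Among 10 measured tonicity-responsive and osmolyte genes, 8 rose and 1 fell over all genes tested, and 8 rose and 2 fell adjusted over the list alone (median log2 change 1.12, adjusted p = 2.69e-08). Akr1b1, the aldose reductase that makes sorbitol, rose by 1.74 ± 0.06 on the log2 scale. Slc5a3, the myo-inositol transporter, rose by 2.34 ± 0.09, and S100a4, a calcium-binding protein, by 2.08 ± 0.12. Nfat5, the transcription factor that drives many tonicity-responsive genes, rose by 0.77 ± 0.11. The taurine transporter gene Slc6a6 had a log2 change of −0.20 ± 0.06 (adjusted p = 0.0163), which missed the threshold after quantile normalization (−0.15, adjusted p = 0.0857), without the arrays numbered 3 and 9 (−0.17, adjusted p = 0.0807) and without steady 300 replicate 1 (−0.19) or 3 (−0.19) or steady 600 replicate 3 (−0.18). Over its alternatives the adjusted p lay between 6.20e-04 and 0.0857. Of 17 measured chaperone genes, 6 rose and 2 fell over all genes tested, and 7 rose and 2 fell adjusted over the list alone. That list's call (adjusted p = 0.0112) was lost at adjusted p = 0.0910 with an estimated correlation. Hspa2 rose by 1.79 ± 0.09, the osmotic stress protein gene Hspa4l by 1.46 ± 0.10 and Hsph1 by 0.88 ± 0.08.

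Of 19 measured collecting duct genes, 13 were higher and 2 lower over all genes tested, and 14 and 2 adjusted over the list alone (median 1.38, adjusted p = 7.57e-14). They included the transcription factor gene Elf5 (4.05 ± 0.17) and Fxyd4, a regulator of the sodium pump (4.14 ± 0.21). Loop and proximal tubule markers rose beside them (median 0.20, adjusted p = 4.22e-04), with 5 of 11 higher by either adjustment. These included the water channel gene Aqp1 (3.25 ± 0.13), known from the proximal tubule and thin descending limb, and the claudin gene Cldn10 (2.70 ± 0.10). Interferon-stimulated genes were higher in 18 of 19 cases and lower in 1, also when adjusted over the list alone (median 1.35, adjusted p = 8.26e-18). Mx1, an interferon-induced GTPase, rose by 4.08 ± 0.24 and the interferon regulatory factor Irf7 by 2.40 ± 0.13.

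Of 21 measured cytokine and NF-kB target genes, 18 were lower and 1 was higher, with the same counts adjusted over the list alone (median −1.07, adjusted p = 8.26e-18). Cxcl1 changed by −3.77 ± 0.10 and Il1b by −4.33 ± 0.15. Leukocyte markers were lower beside them, 10 of 12 by either adjustment (median −1.20, adjusted p = 1.67e-09). Fibroblast markers had 8 lower and 2 higher of 13 by either adjustment (median −0.38, adjusted p = 0.00502, and adjusted p = 0.206 with an estimated correlation). Matricellular genes had 8 lower and 1 higher of 12 by either adjustment (median −0.42, adjusted p = 5.20e-04, and adjusted p = 0.206 with an estimated correlation). Endothelial markers had 5 higher and 3 lower of 10 by either adjustment (median 0.28, adjusted p = 0.0288, and adjusted p = 0.430 with an estimated correlation). The macrophage marker Cd68 changed by −1.95 ± 0.11 and Laptm5, of blood cell lysosomes, by −1.40 ± 0.11. Vsig4, a complement receptor of macrophages, changed by −4.93 ± 0.14 and the chemokine gene Ccl6 by −5.14 ± 0.14. The remaining genes among the largest changes were Lypd2 (4.98 ± 0.16), the protease inhibitor gene Serpina3n (4.21 ± 0.14) and Dlgap5l2 (−6.21 ± 0.16). In all, 1989 genes were higher and 1946 lower, of which 301 and 350 changed at least 2-fold. The share of lower genes was 49.5%, but 52.5% after median centring and 54.2% with cyclic loess.

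The same groups were followed to 900 mosmol/kg by comparing steady 900 with steady 300. Aqp2 stood at 12.04 ± 0.07 (SD, n = 3), a log2 change of 6.44 ± 0.20 or 86.6-fold, and Slc14a2 rose 75.3-fold. Fibroblast markers and matricellular genes were again lower, together with the cytokine genes and leukocyte markers. Of 19 collecting duct genes, 15 rose and 2 fell, and 16 and 2 did so adjusted over the list alone (median 2.01, adjusted p = 5.61e-10). Avpr2 rose by 4.25 ± 0.12 and Elf5 48.6-fold. Loop and proximal tubule markers rose too, 4 of 11 by either adjustment (median 0.16, adjusted p = 0.00212).

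Of the 10 tonicity genes, 8 rose and 2 fell, also adjusted over the list alone (median 1.7, adjusted p = 1.04e-06). Slc5a3 rose 14.5-fold, S100a4 10.4-fold, Akr1b1 5.04-fold and Nfat5 2.09-fold, and Slc6a6 changed by −0.34 ± 0.06. Chaperone genes were higher in 7 and lower in 2 of 17 cases by either adjustment, but the list's call (adjusted p = 0.0374) was lost at adjusted p = 0.144 with an estimated correlation and at adjusted p = 0.0523 without steady 900 replicate 2, the range over its alternatives being 0.0165 to 0.144. Hspa2 rose by 2.91 ± 0.09, Hspa4l by 2.67 ± 0.10 and Hsph1 by 1.91 ± 0.08. Interferon-stimulated genes rose in 18 of 19 cases and fell in 1, also adjusted over the list alone (median 2.01, adjusted p = 6.16e-13), with Mx1 up by 5.53 ± 0.24 and Irf7 by 3.67 ± 0.13.

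Cytokine genes were lower in 18 and higher in 2 of 21 cases, also adjusted over the list alone (median −1.84, adjusted p = 9.06e-10). Il1a changed by −6.79 ± 0.19, Cxcl1 by −4.11 ± 0.10 and Cxcl6 by −7.34 ± 0.18. Proliferation genes had 19 higher of 23, or 20 adjusted over the list alone (median 0.69, adjusted p = 3.72e-08, and adjusted p = 0.0741 with an estimated correlation). Leukocyte markers fell in 11 of 12 cases by either adjustment (median −1.46, adjusted p = 1.28e-07). Fibroblast markers fell in 10 of 13 cases by either adjustment (median −1.87, adjusted p = 2.45e-10), among them the matrix protein gene Postn (−5.66 ± 0.13) and the surface glycoprotein gene Thy1 (−4.25 ± 0.10). Matricellular genes fell beside them in 10 of 12 cases by either adjustment (median −1.79, adjusted p = 1.92e-09). Ankrd1 changed by −4.61 ± 0.11 and Ccn1 by −2.64 ± 0.08, both known targets of YAP. The largest changes also included Lypd2 (6.03 ± 0.16), Vsig4 (−7.50 ± 0.14), Dlgap5l2 (−6.55 ± 0.16) and Il1rl1, the interleukin 33 receptor gene (−6.30 ± 0.14). In all, 2927 genes were higher and 3228 lower, of which 693 and 794 changed at least 2-fold.

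Steady 900 also differed from steady 600, with 1641 genes higher and 1876 lower. The share of lower genes was 53.3%, but 48.5% after median centring and 46.45% with cyclic loess, so which direction prevailed turned with the scaling. Proliferation genes were higher in 23 of 23 cases by either adjustment (median 0.89, adjusted p = 1.11e-21). Matricellular genes fell in 10 of 12 cases (median −1.18, adjusted p = 3.30e-15) and fibroblast markers in 11 of 13 (median −1.48, adjusted p = 8.71e-20), with the same counts adjusted over each list alone. Leukocyte markers had 5 lower of 12 by either adjustment (median −0.23, adjusted p = 0.0209, and adjusted p = 0.309 with an estimated correlation). That call was also lost without steady 900 replicate 2 (−0.23, adjusted p = 0.0529), and the adjusted p over the alternatives lay between 0.00750 and 0.309. The largest increases were in the collagenase gene Mmp13 (3.13 ± 0.17) and in Guca2a and Guca2b, which encode guanylin and uroguanylin (2.91 ± 0.18 and 2.51 ± 0.12). The largest decreases were in Il1rl1 (−4.66 ± 0.14), Thy1 (−3.48 ± 0.10) and the collagen gene Col11a1 (−3.42 ± 0.10). Of the genes higher in steady 600 than in steady 300, 862 were higher again in steady 900, against 225 for independent lists, and 875 were lower at both steps, against 252. A further 174 rose and then fell, and 117 fell and then rose, against 257 and 220. The steady 600 arrays enter both steps with opposite sign, which lowers the counts of shared direction.

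**Figure D2:**
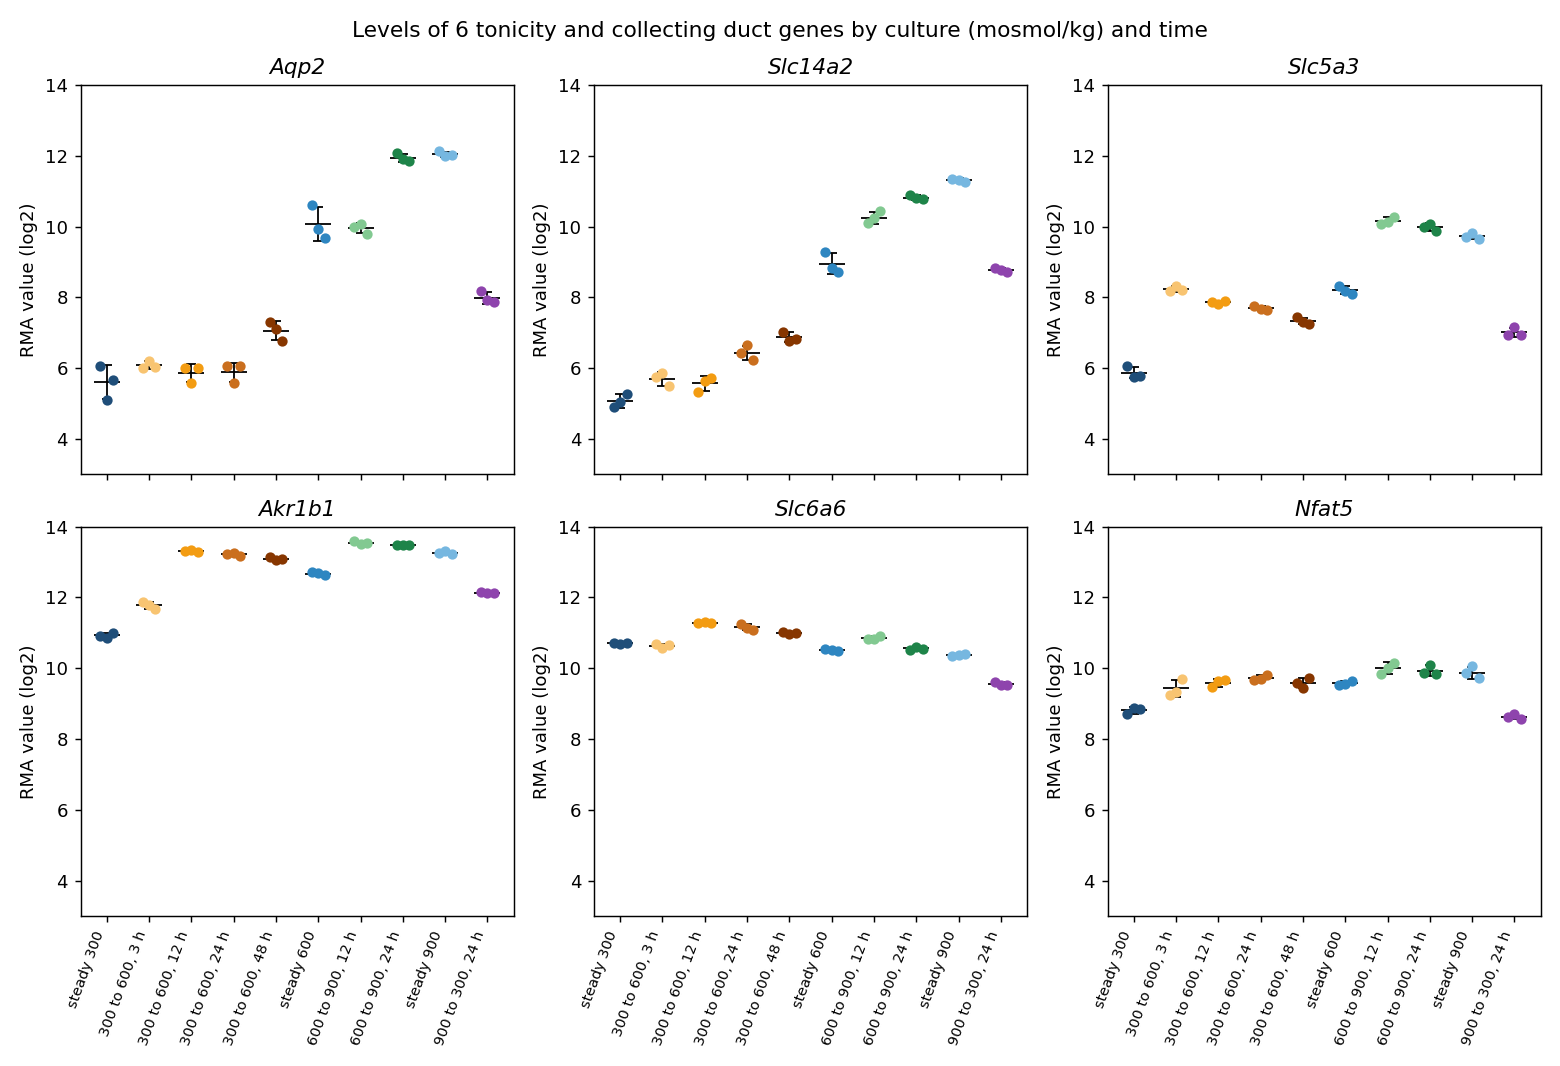
RMA values (log2, vertical axes from 3 to 14) of 6 genes in the 10 groups along the horizontal axes; points are arrays, bars the mean ± SD of 3 arrays. Aqp2 and Slc14a2 differed most between the steady cultures, while Akr1b1 was near 13 from 12 h onward after the step from 300 to 600.

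The acute response to a step from 300 to 600 mosmol/kg was followed over time against steady 300. At 3 h, immediate early, tonicity-responsive and collecting duct genes were higher. The myo-inositol transporter gene Slc5a3 rose from 5.87 ± 0.16 to 8.24 ± 0.08 (SD, n = 3), 5.16-fold. Of 17 immediate early genes, 14 rose over all genes tested and 15 adjusted over the list alone (median 0.69, adjusted p = 5.45e-13). The transcription factor genes Egr1 and Klf4 rose by 2.54 ± 0.17 and 1.29 ± 0.09. Of the 10 tonicity genes, 8 rose by either adjustment (median 0.64, adjusted p = 3.03e-08). Akr1b1 rose by 0.86 ± 0.06, the amino acid transporter gene Slc38a2 by 0.92 ± 0.08, Hspa4l by 0.66 ± 0.10 and Nfat5 by 0.61 ± 0.11. Slc6a6 had a log2 change of −0.07 ± 0.06 (adjusted p = 0.388).

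Collecting duct genes were higher in 8 and lower in 1 of 19 cases at 3 h, or 9 and 1 adjusted over the list alone (median 0.25, adjusted p = 2.40e-04). These included the water channel gene Aqp4 (1.18 ± 0.14), the prostaglandin E receptor genes Ptger1 (0.68 ± 0.12) and Ptger3 (0.48 ± 0.09), and Slc14a2 (0.63 ± 0.13). In steady 300 they stood low, at 6.41, 5.57, 5.33 and 5.07. Among the dimmest of 3 equal groups of genes by brightness, 675 of 854 changed genes were higher at 3 h. Part of such rises may therefore come from the signal range, which was not tested for this list. Loop and proximal tubule markers rose with the collecting duct genes in 5 of 11 cases by either adjustment (median 0.20, adjusted p = 2.92e-04), with Aqp1 at 1.14 ± 0.13 and Cldn10 at 0.97 ± 0.10. Aqp2 had a log2 change of 0.48 ± 0.20 (adjusted p = 0.0563), which passed the threshold without steady 300 replicate 1 (0.71, adjusted p = 0.00741) and with cyclic loess normalization (0.66, adjusted p = 0.0137). It also passed with the replicate number as a block (adjusted p = 0.0271), with a trended and robust variance (adjusted p = 0.0381) and with the filter on dim genes (adjusted p = 0.0479). Over its alternatives the adjusted p lay between 0.00741 and 0.421, the highest without steady 300 replicate 2.

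Of 23 proliferation genes, 18 fell and 1 rose at 3 h, or 19 and 1 adjusted over the list alone, but the list's call (median −0.52, adjusted p = 5.04e-05) was lost at adjusted p = 0.294 with an estimated correlation. The mitotic kinase gene Ttk changed by −1.04 ± 0.10 and the cyclin gene Ccnb1 by −1.13 ± 0.13. Among chaperone genes 4 of 17 rose and 1 fell by either adjustment (adjusted p = 0.321 for the list). Hspa2 rose by 0.67 ± 0.09 and Hsph1 by 0.60 ± 0.08, and the heat shock factor gene Hsf2 changed by −0.88 ± 0.13. Cholesterol genes fell in 10 of 15 cases by either adjustment (median −0.30, adjusted p = 0.00966, and adjusted p = 0.144 with an estimated correlation). After quantile normalization that median was −0.13 (adjusted p = 0.118), and over the alternatives the adjusted p lay between 0.00638 and 0.185. Other large changes were in the GTPase gene Rrad (3.22 ± 0.11), the glycogen phosphorylase gene Pygm (2.68 ± 0.10), Rnf186 (−2.46 ± 0.09), the lysophosphatidic acid receptor gene Lpar6 (−2.45 ± 0.15) and Zfp26 (−2.28 ± 0.11). In all, 1759 genes were higher and 4282 lower at 3 h, 6041 together, and the number was 4470 with only the compared arrays in the fit. Of the 6041 changed genes, 70.9% were lower. That share was 58.3% after quantile normalization and 59.1% with cyclic loess, and it was 20.96% among the dimmest of 3 equal groups of genes by brightness against 85.6% among the brightest. Replicate 3 at 3 h stood apart from replicates 1 and 2, with median absolute differences of 0.205 and 0.198 against 0.122 between those.

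At 12 h, tonicity-responsive genes were higher and cholesterol genes were lower. Akr1b1 rose from 10.93 ± 0.07 to 13.32 ± 0.02 (SD, n = 3), 5.23-fold, and Hspa4l rose 8.95-fold. Tonicity genes rose in 8 of 10 cases by either adjustment (median 0.67, adjusted p = 4.86e-10), including Slc5a3 (1.99 ± 0.09), Nfat5 (0.77 ± 0.11) and Slc6a6 (0.58 ± 0.06). Chaperone genes rose in 7 and fell in 3 of 17 cases, or 8 and 4 adjusted over the list alone, with Hsph1 3.11-fold and Hspa2 2.83-fold higher. That list's call (adjusted p = 0.00487) was lost at adjusted p = 0.130 with an estimated correlation. Cholesterol genes fell in 13 of 15 cases by either adjustment (median −0.56, adjusted p = 7.82e-07), among them Fdft1 (−0.99 ± 0.09) and Sqle (−0.89 ± 0.09), which encode squalene synthase and squalene epoxidase. Interferon-stimulated genes fell in 13 of 19 cases and rose in 1, or 14 and 2 adjusted over the list alone (median −0.64, adjusted p = 4.44e-05, and adjusted p = 0.147 with an estimated correlation). The immunoproteasome genes Psmb9 and Psmb8 changed by −1.18 ± 0.10 and −0.84 ± 0.08.

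Collecting duct genes went both ways at 12 h, with 4 higher and 5 lower of 19, or 5 and 5 adjusted over the list alone (median 0.06, mean −0.12, adjusted p = 0.979). Slc14a2 rose by 0.50 ± 0.13 and Aqp2 had a log2 change of 0.26 ± 0.20 (adjusted p = 0.346). The transcription factor gene Gata3 changed by −1.27 ± 0.12, Aqp4 by −0.82 ± 0.14 and the endothelin gene Edn1 by −0.66 ± 0.11. Fibroblast markers fell in 8 of 13 cases, or 10 adjusted over the list alone (median −0.32, adjusted p = 8.77e-04, and adjusted p = 0.153 with an estimated correlation). General epithelial markers had 6 lower and 2 higher of 12 by either adjustment (median −0.25, adjusted p = 0.0229, and adjusted p = 0.385 with an estimated correlation). Without replicate 3 at 12 h that call was lost too (−0.19, adjusted p = 0.0591), the range over its alternatives being 0.00353 to 0.385. Endothelial markers fell in 6 of 10 cases, or 7 adjusted over the list alone (median −0.61, adjusted p = 8.77e-04, and adjusted p = 0.210 with an estimated correlation). Postn changed by −1.54 ± 0.13 and the collagen gene Col3a1 by −0.61 ± 0.08. The largest changes were in Prss35, a serine protease family member (4.82 ± 0.11), Mmp13 (3.14 ± 0.17), the immune checkpoint gene Vtcn1 (−3.04 ± 0.07), the GABA receptor gene Gabrp (−2.83 ± 0.15) and the amino acid transporter gene Slc6a14 (−2.69 ± 0.17). In all, 1729 genes were higher and 3282 lower, and 301 of the lower genes changed at least 2-fold against 89 of the higher. The share of lower genes was 65.5%, or 59.05% after quantile normalization and 63.7% with cyclic loess. It was 40.7% among the dimmest of 3 equal groups of genes by brightness, 71.35% in the middle group and 66.1% among the brightest.

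Between 3 and 12 h, 3352 genes rose and 2587 fell, 5939 together, and the number was 4047 with only the compared arrays in the fit. The share of lower genes was 43.6%, but 55.1% with cyclic loess, so which direction prevailed turned with the scaling. Immediate early genes fell in 12 of 17 cases by either adjustment (median −0.50, adjusted p = 5.22e-05, and adjusted p = 0.179 with an estimated correlation). Endothelial markers fell in 8 of 10 cases by either adjustment (median −0.41, adjusted p = 5.58e-04, and adjusted p = 0.179 with an estimated correlation). Fibroblast markers had 6 lower and 1 higher of 13, or 7 and 1 adjusted over the list alone (median −0.20, adjusted p = 0.0256, and adjusted p = 0.302 with an estimated correlation). That call was also lost without replicate 3 at 3 h (−0.16, adjusted p = 0.0846) or replicate 2 at 12 h (−0.17, adjusted p = 0.0518), with a range over the alternatives of 0.00781 to 0.302. Prss35 rose by 3.33 ± 0.11 and the lymphocyte activation gene Cd69 by 2.59 ± 0.12, and Hspa4l rose 5.67-fold. Tmem45b, Tspan1 and Ly6c changed by −2.63 ± 0.11, −2.52 ± 0.11 and −2.41 ± 0.17.

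At 24 h, tonicity genes remained higher and proliferation genes, fibroblast markers and leukocyte markers were lower. Akr1b1 stood at 13.22 ± 0.03 (SD, n = 3), 4.89-fold above steady 300, and Hspa4l was 5.55-fold higher. Tonicity genes were higher in 9 of 10 cases by either adjustment (median 0.72, adjusted p = 1.26e-12), including Slc5a3 (1.82 ± 0.09), Slc14a2 (1.35 ± 0.13), Nfat5 (0.92 ± 0.11) and Slc6a6 (0.45 ± 0.06). Proliferation genes were lower in 21 of 23 cases by either adjustment (median −1.05, adjusted p = 3.61e-23), with Ttk at −2.09 ± 0.10 and the cyclin gene Ccna2 at −1.93 ± 0.13. Fibroblast markers were lower in 10 of 13 cases, or 11 adjusted over the list alone (median −1.17, adjusted p = 2.22e-13), with Postn at −2.42 ± 0.13 and Col3a1 at −1.08 ± 0.08. Leukocyte markers were lower in 8 of 12 cases, or 10 adjusted over the list alone (median −1.11, adjusted p = 1.84e-11), with Cd68 at −2.19 ± 0.11 and Tyrobp, an adaptor of myeloid receptors, at −2.10 ± 0.14. Endothelial markers had 5 lower and 1 higher of 10 by either adjustment (median −0.35, adjusted p = 0.00719, and adjusted p = 0.273 with an estimated correlation).

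Collecting duct genes rose in 4 and fell in 1 of 19 cases at 24 h, or 4 and 3 adjusted over the list alone (median 0.09, adjusted p = 0.222). Beside them, 5 of 11 loop and proximal tubule markers were higher by either adjustment (median 0.13, adjusted p = 0.00719, and adjusted p = 0.107 with an estimated correlation). The transcription factor genes Tfap2b and Hoxd10 rose by 0.52 ± 0.10 and 0.45 ± 0.09, and Aqp2 had a log2 change of 0.29 ± 0.20 (adjusted p = 0.361). Chaperone genes rose in 4 and fell in 2 of 17 cases, or 7 and 3 adjusted over the list alone (adjusted p = 0.0154, and adjusted p = 0.128 with an estimated correlation). Hspa2 rose by 1.20 ± 0.09 and Hsph1 by 1.04 ± 0.08. The largest changes were in Mmp13 (4.56 ± 0.17), the protease inhibitor gene Serpinb2 (3.56 ± 0.18), Prss35 (3.45 ± 0.11), Ccl6 (−3.84 ± 0.14), the Fc receptor gene Fcgr2b (−3.50 ± 0.17) and Pi15 (−3.33 ± 0.18). In all, 1363 genes were higher and 1879 lower, 3242 together, and the number was 4994 with array weights. Of the genes changed at least 2-fold, 68 were higher and 365 lower.

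At 48 h Aqp2 had risen from 5.61 ± 0.49 to 7.06 ± 0.27 (SD, n = 3), 2.73-fold, against 22.1-fold in steady 600. Slc14a2 had risen by 1.80 ± 0.13 and Hoxd10 by 0.62 ± 0.09. Collecting duct genes were higher in 7 and lower in 2 of 19 cases, or 9 and 4 adjusted over the list alone (median 0.21, adjusted p = 0.0187, and adjusted p = 0.0563 with an estimated correlation). Loop and proximal tubule markers were higher in 5 of 11 cases by either adjustment (median 0.20, adjusted p = 0.00222, and adjusted p = 0.0555 with an estimated correlation). Of the 10 tonicity genes, 8 were higher, or 9 adjusted over the list alone (median 0.73, adjusted p = 2.03e-11). Akr1b1 was 4.50-fold higher, Hspa4l 3.88-fold, Slc5a3 2.75-fold, Nfat5 1.72-fold and Slc6a6 1.23-fold. Chaperone genes were higher in 5 and lower in 2 of 17 cases, or 6 and 2 adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.122 with an estimated correlation), with Hspa2 at 1.39 ± 0.09 and Hsph1 at 0.96 ± 0.08.

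Proliferation genes were lower in 21 of 23 cases at 48 h, or 22 adjusted over the list alone (median −1.48, adjusted p = 3.04e-31), with Ttk at −2.10 ± 0.10 and the ribonucleotide reductase gene Rrm2 at −2.14 ± 0.13. Fibroblast markers were lower in 11 of 13 cases by either adjustment (median −0.66, adjusted p = 6.09e-14), with Postn at −3.73 ± 0.13 and Col1a2 at −1.53 ± 0.10. Leukocyte markers were lower in 9 of 12 cases, or 10 adjusted over the list alone (median −1.03, adjusted p = 2.03e-11), with Cd68 at −2.18 ± 0.11 and the lysozyme gene Lyz2 at −2.01 ± 0.11. Cytokine genes went both ways, with 6 higher and 8 lower of 21, or 8 and 9 adjusted over the list alone (median −0.03, adjusted p = 0.366). The largest changes were in Prss35 (3.50 ± 0.11), Ly6al (2.80 ± 0.29), Clca4l (2.72 ± 0.18), Vsig4 (−5.45 ± 0.14), Ccl6 (−4.45 ± 0.14) and the transferrin gene Tf (−4.32 ± 0.13). In all, 1388 genes were higher and 1740 lower, 3128 together, and the number was 5130 with array weights. At least 2-fold changes were found in 82 of the higher and 303 of the lower genes. The share of lower genes was 55.6%, but 48.5% after median centring.

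Between 12 and 48 h, 2871 genes rose and 1577 fell, of which 188 and 150 changed at least 2-fold. Proliferation genes fell in 22 of 23 cases, or 23 adjusted over the list alone (median −0.97, adjusted p = 9.49e-24), and cholesterol genes rose in 12 of 15, or 13 adjusted over the list alone (median 0.46, adjusted p = 8.04e-07). Leukocyte markers fell in 8 of 12 cases by either adjustment (median −1.38, adjusted p = 1.32e-10). Fibroblast markers fell in 6 of 13 (median −0.14, adjusted p = 3.37e-05, and adjusted p = 0.0585 with an estimated correlation) and endothelial markers rose in 5 of 10 (median 0.41, adjusted p = 5.23e-04, and adjusted p = 0.147 with an estimated correlation), with the same counts adjusted over each list alone. Ly6al, the matrix protein gene Aspn and Ly6i rose by 3.81 ± 0.29, 3.06 ± 0.17 and 2.64 ± 0.19, and Vsig4, Tf and Ccl6 changed by −5.61 ± 0.14, −4.58 ± 0.13 and −3.65 ± 0.14.

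**Figure D3:**
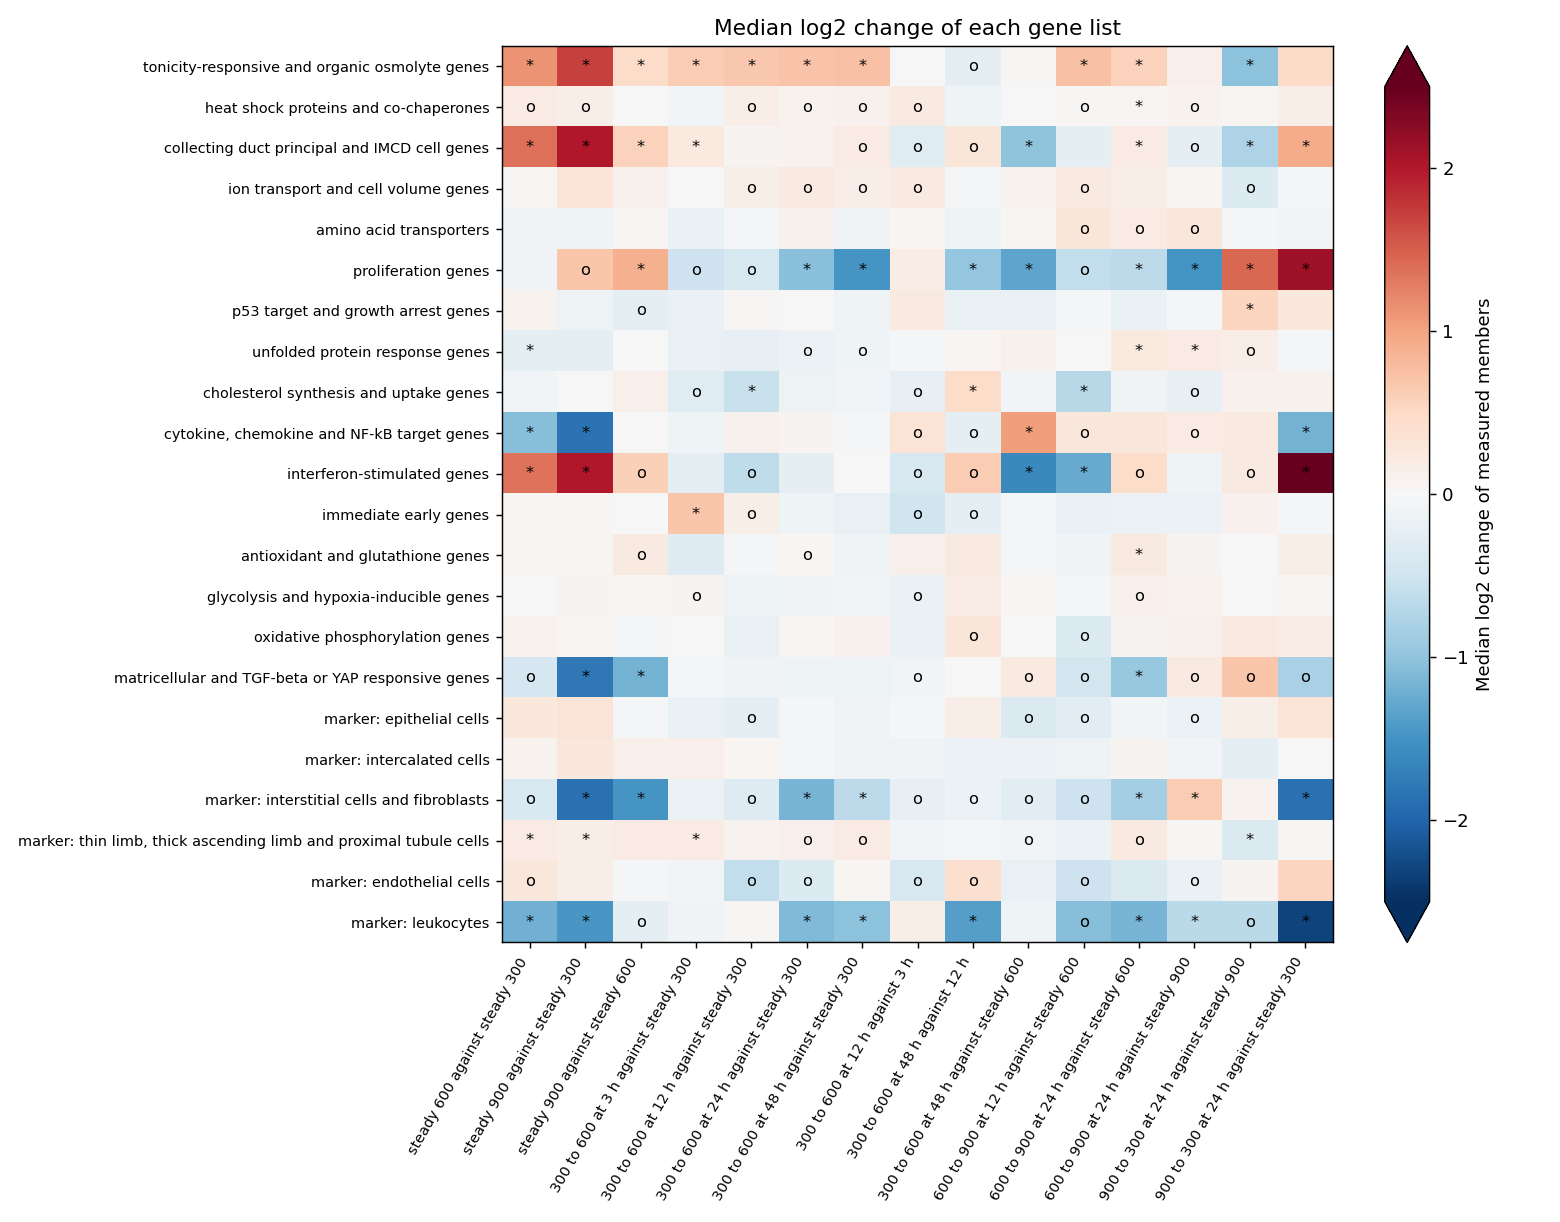
Median log2 change of the measured members of 22 gene lists (rows of the map) in 15 comparisons (columns), with colour from blue (lower) to red (higher) and capped at ±2.5. An asterisk marks a list with an adjusted p under 0.05 both at the preset and at an estimated correlation, and a circle a list past it only at the preset correlation.

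Whether cells at 48 h after the step had reached the steady 600 profile was asked by comparing both directly. Interferon-stimulated genes, collecting duct genes and proliferation genes were lower at 48 h than in steady 600, and cytokine genes were higher. Cxcl6 was 72.5-fold higher, at 12.61 ± 0.09 against 6.43 ± 0.42 (SD, n = 3). Dlgap5l2 and the olfactomedin gene Olfm4 were higher by 5.77 ± 0.16 and 5.74 ± 0.14, and Gabrp, Fxyd4 and Elf5 differed by −3.78 ± 0.15, −3.71 ± 0.21 and −3.45 ± 0.17. Interferon-stimulated genes were lower in 18 and higher in 1 of 19 cases by either adjustment (median −1.61, adjusted p = 4.06e-22). Collecting duct genes were lower in 13 and higher in 2 of 19 cases, or 14 and 2 adjusted over the list alone (median −1.0, adjusted p = 3.60e-13). Other cell type markers were lower beside them, each at the preset correlation only. General epithelial markers had 8 lower and 2 higher of 12, or 9 and 3 adjusted over the list alone (median −0.36, adjusted p = 0.00438, and adjusted p = 0.219 with an estimated correlation). Fibroblast markers had 7 lower and 1 higher of 13 by either adjustment (median −0.29, adjusted p = 5.27e-05, and adjusted p = 0.0833 with an estimated correlation). Of the loop and proximal tubule markers 5 of 11 were lower by either adjustment (median −0.06, adjusted p = 0.0180, and adjusted p = 0.154 with an estimated correlation). Proliferation genes were lower in 22 of 23 cases by either adjustment (median −1.31, adjusted p = 1.04e-27). Cytokine genes were higher in 16 and lower in 3 of 21 cases, or 17 and 3 adjusted over the list alone (median 1.04, adjusted p = 1.27e-17), while leukocyte markers had a median of −0.10 (2 higher and 2 lower of 12, or 2 and 3 adjusted over the list alone, adjusted p = 0.794). In all, 1373 genes were higher and 1812 lower, of which 136 and 331 differed at least 2-fold. The share of lower genes was 56.9%, but 46.9% after median centring, so which direction prevailed turned with the scaling.

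Changes at 48 h and in steady 600, both against steady 300, correlated across genes at r = 0.581, where unchanged groups against the same controls gave 0.502 in simulations. Their covariance was 0.101 against a simulated 0.00637. Of the genes higher in steady 600, 741 were also higher at 48 h, against 190 for independent lists, and 990 were lower in both, against 233. Changes at 3 h and at 48 h correlated at r = 0.279, with 0.501 in simulations and a covariance of 0.0377 against 0.00636. The simulated groups held noise only, so a simulated r is not the part of the measured r that shared controls add. The covariances can be compared directly. Less the simulated part they were 0.0949 for 48 h with steady 600 and 0.0313 for 3 h with 48 h. The 3 control arrays could not be split into parts of 2 or more, so part of the excess in these overlaps may come from the shared controls.

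To see whether cells already at 600 mosmol/kg responded to a further step, cells at 12 and 24 h after a step from 600 to 900 were compared with steady 600. At 12 h, tonicity genes were higher while interferon-stimulated and cholesterol genes were lower. The adaptor gene Sla rose from 7.10 ± 0.20 to 11.36 ± 0.21 (SD, n = 3), 19.1-fold, and Mmp13 and the cyclooxygenase gene Ptgs2 rose 17.6-fold and 15.1-fold. All 10 measured tonicity genes rose by either adjustment (median 0.73, adjusted p = 2.62e-10). Interferon-stimulated genes fell in 16 of 19 cases, or 17 with 1 higher adjusted over the list alone (median −1.26, adjusted p = 1.71e-11), and cholesterol genes in 13 of 15 by either adjustment (median −0.69, adjusted p = 5.07e-07). Proliferation genes fell in 19 of 23 cases by either adjustment (median −0.62, adjusted p = 1.51e-08, and adjusted p = 0.106 with an estimated correlation). Leukocyte markers fell in 11 of 12 cases by either adjustment (median −1.07, adjusted p = 1.45e-06, and adjusted p = 0.0595 with an estimated correlation). Fibroblast markers fell in 10 and rose in 1 of 13 cases by either adjustment (median −0.52, adjusted p = 6.45e-04, and adjusted p = 0.126 with an estimated correlation). General epithelial markers had 8 lower and 1 higher of 12, or 9 and 2 adjusted over the list alone (median −0.28, adjusted p = 0.0103, and adjusted p = 0.192 with an estimated correlation). With cyclic loess that call was lost (−0.12, adjusted p = 0.0859), and the range over its alternatives was 0.00462 to 0.192. Endothelial markers had 6 lower and 1 higher of 10, or 7 and 1 adjusted over the list alone (median −0.51, adjusted p = 0.0169, and adjusted p = 0.283 with an estimated correlation). Without replicate 9 at 12 h that call was lost (−0.53, adjusted p = 0.0601), the range over its alternatives being 0.00816 to 0.283. Replicate 9 stood apart from replicates 1 and 2, with median absolute differences of 0.2002 and 0.194 against 0.0971 between those. Ankrd1, the lectin gene Clec4a3 and Mmp7 changed by −3.42 ± 0.11, −3.08 ± 0.15 and −3.01 ± 0.20. In all, 1812 genes were higher and 3672 lower, 67.0% of the changed genes being lower, against 54.3% after quantile normalization, 55.1% after median centring and 55.8% with cyclic loess. With only the compared arrays in the fit, 4307 genes passed in place of 5484.

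At 24 h after the step from 600 to 900, tonicity, chaperone and collecting duct genes were higher. Aqp2 rose from 10.07 ± 0.48 to 11.94 ± 0.12 (SD, n = 3), 3.66-fold, Slc14a2 rose 3.66-fold and Avpr2 3.08-fold, while Edn1 changed by −1.28 ± 0.11. Collecting duct genes rose in 7 and fell in 3 of 19 cases, or 8 and 3 adjusted over the list alone (median 0.21, adjusted p = 0.00748). Loop and proximal tubule markers rose in 4 of 11 cases by either adjustment (median 0.23, adjusted p = 0.00563, and adjusted p = 0.0621 with an estimated correlation). Of the 10 tonicity genes, 6 rose by either adjustment (median 0.58, adjusted p = 3.81e-08), including Hspa4l (2.22 ± 0.10), Slc5a3 (1.77 ± 0.09) and Akr1b1 (0.80 ± 0.06), the last near the top of the measured range. Nfat5 rose by 0.35 ± 0.11 (adjusted p = 0.0143), a call lost without steady 600 replicate 1 (0.33, adjusted p = 0.0518) or without replicate 2 at 24 h (0.27, adjusted p = 0.111), the lowest over its alternatives being 0.00133. Slc6a6 had a log2 change of 0.05 ± 0.06 (adjusted p = 0.645). Interferon-stimulated genes, lower at 12 h, were higher in 12 and lower in 2 of 19 cases at 24 h, or 12 and 3 adjusted over the list alone (median 0.46, adjusted p = 3.93e-04, and adjusted p = 0.1001 with an estimated correlation). Chaperone genes rose in 7 of 17 cases, or in 7 with 1 lower adjusted over the list alone (median 0.03, adjusted p = 0.00242), with Hsph1 at 1.51 ± 0.08 and Hspa2 at 1.29 ± 0.09.

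Proliferation genes fell in 20 of 23 cases at 24 h, or 23 adjusted over the list alone (median −0.65, adjusted p = 1.94e-14), with Ttk at −1.39 ± 0.10 and the thymidylate synthase gene Tyms at −1.0 ± 0.09. Matricellular genes fell in 11 of 12 cases by either adjustment (median −0.95, adjusted p = 7.11e-14), with Ankrd1 at −2.23 ± 0.11 and Ccn1 at −1.91 ± 0.08. Fibroblast markers fell beside them in 11 of 13 cases by either adjustment (median −0.84, adjusted p = 2.37e-11), with the smooth muscle genes Tagln and Acta2 at −1.49 ± 0.10 and −1.46 ± 0.10. Leukocyte markers fell in 10 of 12 cases by either adjustment (median −1.17, adjusted p = 4.13e-11), with the integrin gene Itgam at −2.02 ± 0.13 and Csf1r, a receptor of macrophage growth factor, at −1.57 ± 0.11. The largest increases were in S100a5 (3.40 ± 0.14), Mmp13 (3.06 ± 0.17), Tm6sf1 (3.01 ± 0.10), Sla (2.96 ± 0.10) and the chloride channel subunit gene Bsnd (2.89 ± 0.13). The largest decreases were in Mmp7 (−3.01 ± 0.20), the nucleoside transporter gene Slc28a2 (−2.86 ± 0.16), the cytokine gene Il33 (−2.85 ± 0.22), the tissue factor gene F3 (−2.83 ± 0.11) and the fatty acid receptor gene Cd36 (−2.78 ± 0.16). In all, 1631 genes were higher and 2132 lower, 56.7% of the changed genes being lower, against 46.1% after median centring.

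Against steady 900, the cells at 24 h after the step differed most in proliferation genes, lower in 23 of 23 cases by either adjustment (median −1.49, adjusted p = 2.55e-54). Pbk, the topoisomerase gene Top2a and the centromere gene Cenpk differed by −3.39 ± 0.17, −3.02 ± 0.17 and −2.76 ± 0.16. Ptgs2 was 10.8-fold higher than in steady 900, Thy1 5.94-fold and the neuropeptide Y receptor gene Npy1r 5.09-fold. Fibroblast markers were higher in 9 of 13 cases, or in 10 with 1 lower adjusted over the list alone (median 0.63, adjusted p = 2.02e-10). Leukocyte markers were lower in 7 of 12 cases, or 8 adjusted over the list alone (median −0.68, adjusted p = 2.22e-10). Endothelial markers had 4 lower and 1 higher of 10 by either adjustment (median −0.17, adjusted p = 0.0112, and adjusted p = 0.307 with an estimated correlation). General epithelial markers had 3 lower of 12, or 4 adjusted over the list alone (median −0.14, adjusted p = 0.0361, and adjusted p = 0.324 with an estimated correlation), a call that each of the 3 other scalings also ended. It was lost as well without steady 900 replicate 1 (−0.13, adjusted p = 0.0702) or replicate 1 at 24 h (−0.10, adjusted p = 0.0671), with a range over the alternatives of 0.0173 to 0.324. In all, 1373 genes were higher and 1281 lower, 2654 together, and the number was 4264 with array weights. Of the genes that differed at least 2-fold, 42 were higher and 157 lower. Lower genes made up 48.3%, but 50.6% with cyclic loess.

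The return from 900 to 300 mosmol/kg asked whether the profile of adapted cells reverses, and cells at 24 h were compared with steady 900. Tonicity and collecting duct genes fell, and proliferation and p53 target genes rose. Aqp2 fell from 12.04 ± 0.07 to 7.99 ± 0.17 (SD, n = 3), 16.6-fold, and Slc5a3 fell 6.56-fold. Of the 10 tonicity genes, 9 fell by either adjustment (median −1.02, adjusted p = 9.51e-11). Slc14a2 changed by −2.54 ± 0.13, Nfat5 by −1.25 ± 0.11, Akr1b1 by −1.13 ± 0.06 and Slc6a6 by −0.81 ± 0.06. Collecting duct genes fell in 14 and rose in 1 of 19 cases by either adjustment (median −0.78, adjusted p = 1.19e-07), with Avpr2 at −2.02 ± 0.12. Loop and proximal tubule markers fell beside them in 6 of 11 cases by either adjustment (median −0.36, adjusted p = 3.10e-04), with Aqp1 at −3.13 ± 0.13 and Cldn10 at −1.91 ± 0.10. Chaperone genes went both ways, with 4 higher and 5 lower of 17 by either adjustment (median 0.05, mean −0.22, adjusted p = 0.466). Hspa2 changed by −2.08 ± 0.09, Hsph1 by −1.30 ± 0.08 and Hspa4l by −1.19 ± 0.10.

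Proliferation genes rose in 23 of 23 cases by either adjustment (median 1.43, adjusted p = 3.01e-22), with the mitotic kinase genes Aurkb at 2.08 ± 0.11 and Ttk at 1.77 ± 0.10. The p53 target and growth arrest genes rose in 11 and fell in 1 of 16 cases, or 12 and 2 adjusted over the list alone (median 0.53, adjusted p = 1.84e-04). The death receptor gene Fas rose by 1.76 ± 0.13, and Sesn1, a stress-induced regulator of growth, changed by −1.13 ± 0.07. Leukocyte markers fell in 7 and rose in 1 of 12 cases, or 9 and 1 adjusted over the list alone (median −0.68, adjusted p = 1.84e-04, and adjusted p = 0.112 with an estimated correlation). Lyz2 changed by −2.61 ± 0.11 and Csf1r by −1.99 ± 0.11. The largest increases were in Il33 (3.14 ± 0.22), F3 (2.83 ± 0.11), Prl8a9 (2.76 ± 0.17), the cytokine gene Il24 (2.63 ± 0.09) and the lipoxygenase gene Alox5 (2.47 ± 0.13). The largest decreases also included Lypd2 (−3.02 ± 0.16), Bsnd (−2.90 ± 0.13) and Prss35 (−2.90 ± 0.11). In all, 2795 genes were higher and 2678 lower.

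Of the 1989 genes higher in steady 600 than in steady 300, 1053 fell after the return to 300, against 367 for independent lists, and of the 1946 lower genes 816 rose, against 375. These comparisons share no array, and their changes correlated across genes at r = −0.364. The returned cells nevertheless differed from steady 300 in 6180 genes, 2953 higher and 3227 lower. Lower genes made up 52.2%, but 46.8% after median centring. Of the 2927 genes higher in steady 900 than in steady 300, 1742 were still higher than in steady 300 after the return, against 596 for independent lists, and of the 3228 lower genes 2156 were still lower, against 718. Steady 300 enters both comparisons, so part of that excess may come from shared controls.

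Against steady 300, interferon-stimulated genes were higher in 18 and lower in 1 of 19 cases after the return (median 2.78, adjusted p = 3.28e-17) and proliferation genes in 23 of 23 (median 2.12, adjusted p = 2.02e-25), with the same counts adjusted over each list alone. Collecting duct genes were still higher in 13 and lower in 2 of 19 cases by either adjustment (median 0.92, adjusted p = 3.17e-06). Leukocyte markers were lower in 11 of 12 cases by either adjustment (median −2.32, adjusted p = 4.51e-12), fibroblast markers in 12 of 13 (median −1.87, adjusted p = 2.08e-12) and cytokine genes in 18, with 3 higher, of 21 (median −1.18, adjusted p = 2.89e-11). The largest increases were in the prostaglandin reductase gene Ptgr1 (5.30 ± 0.16), Mx1 (4.91 ± 0.24) and Irf7 (4.32 ± 0.13), and the largest decreases in Vsig4 (−7.60 ± 0.14), Cxcl6 (−6.41 ± 0.18) and Dlgap5l2 (−5.98 ± 0.16).

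**Figure D4:**
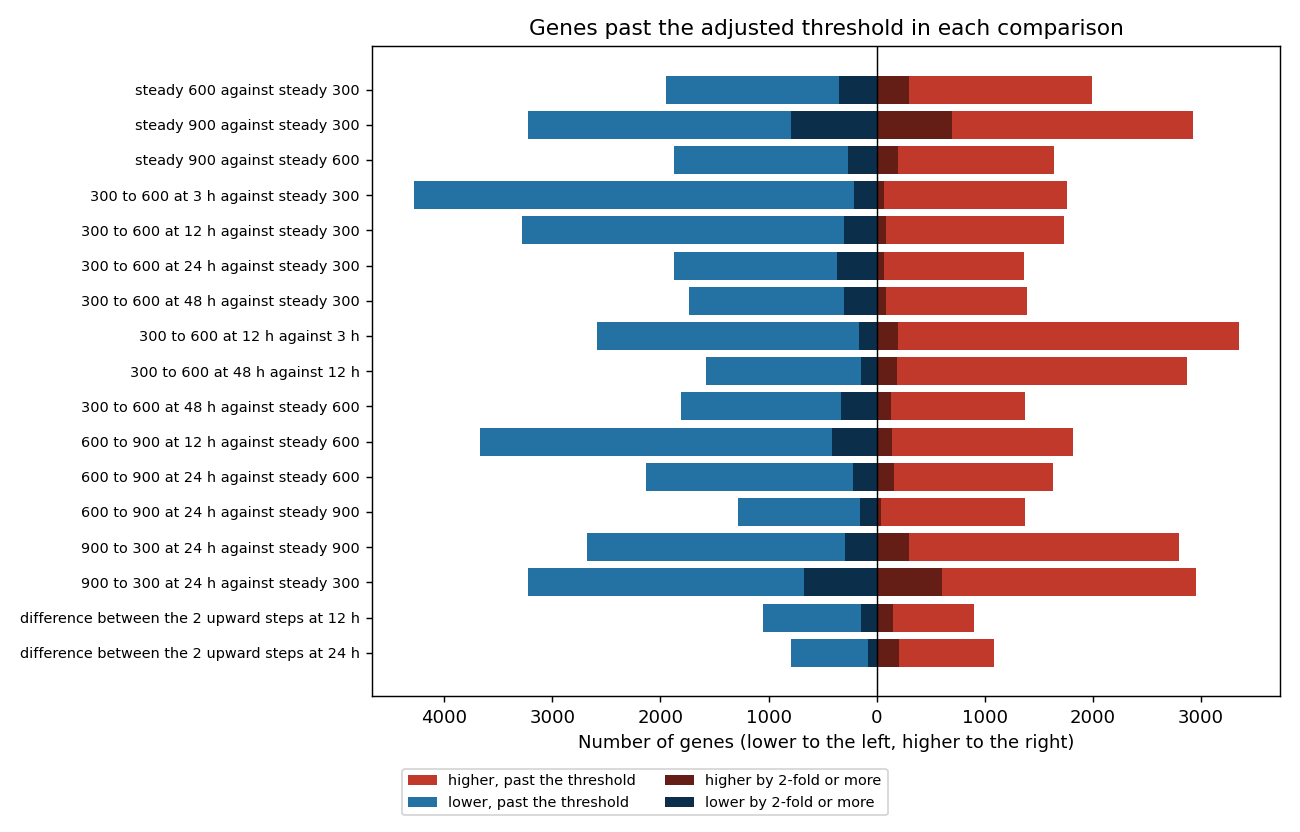
Number of genes past the adjusted threshold in each of 17 comparisons (horizontal axis, lower genes to the left and higher genes to the right of 0), with darker parts for genes changed at least 2-fold. The longest bar to the left is that of 3 h after the step from 300 to 600, with 4282 lower genes.

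The responses to the steps from 300 to 600 and from 600 to 900 mosmol/kg were set against each other at 24 h and at 12 h. At 24 h their changes correlated across genes, which are not independent replicates, at r = 0.565, with no array in common. A set of 604 genes rose after both steps, against 153 for independent lists, and 988 fell after both, against 276. The difference between the steps itself passed the threshold in 1877 genes at 24 h, 1085 with a more positive and 792 with a more negative change in the step to 900, of which 204 and 85 differed at least 2-fold. The chemokine genes Ccl6 and Ccl3 and the channel subunit gene Bsnd differed by 3.66 ± 0.20, 2.89 ± 0.21 and 2.55 ± 0.19. Ccl6 stood at 3.75 in steady 600 and at 3.56 after the step to 900, near the bottom of the scale, so it could hardly fall further and its difference restates the fall from 8.89 to 5.05 in the step to 600. Negative differences were found in Mmp3, the kidney injury gene Havcr1 and Serpinb2, at −2.96 ± 0.20, −2.90 ± 0.20 and −2.42 ± 0.25. With only the compared arrays in the fit the number was 2976, and with array weights 3468.

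At 12 h the difference between the steps passed the threshold in 1947 genes, 896 more positive and 1051 more negative in the step to 900. The share of negative differences, 54.0%, was 43.9% after quantile normalization, 37.5% after median centring and 39.4% with cyclic loess, so which direction prevailed turned with the scaling. S100a5, Sla and the neuropeptide Y receptor gene Npy4r differed by 4.02 ± 0.20, 3.50 ± 0.14 and 3.29 ± 0.19, and Vsig4, Slc28a2 and Clec4a3 by −2.67 ± 0.20, −2.54 ± 0.22 and −2.46 ± 0.21. With array weights the number was 3647.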

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

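The tests of explanations for the collecting duct and cytokine genes, and cyclic loess normalization, were chosen only after the result was seen. The first results that stand out are differences between the step from 600 to 900 and the step from 300 to 600, each tested in limma as the difference itself, with negative values for a more negative change in the step to 900. At 12 h 1947 genes differed. Akr1b1 differed by −1.51, since it rose by 2.39 in the step to 600 and by 0.88 in the step to 900, where it stood at 13.55, near the highest value of the table at 13.88. Slc14a2 differed by 0.81. The list counts are of genes that differed, over all genes and then adjusted over the list alone. Leukocyte markers had 10 of 12 lower by either adjustment (median −1.14, adjusted p = 0.0126 with an estimated correlation). Interferon-stimulated genes had 11 of 19 lower, or 12 (median −0.52, adjusted p = 0.0320 with an estimated correlation), and unfolded protein response genes 7 of 18 higher by either adjustment (median 0.16, adjusted p = 0.0320 with an estimated correlation). The other lists passed only at the preset correlation. Proliferation genes had 10 of 23 lower, or 13 with 1 higher (median −0.45, adjusted p = 0.140 with an estimated correlation). Immediate early genes had 7 of 17 lower by either adjustment (median −0.30, adjusted p = 0.277 with an estimated correlation). Glycolysis and hypoxia genes had 5 of 18 higher by either adjustment (median 0.13, adjusted p = 0.140 with an estimated correlation). Matricellular genes had 9 of 12 lower, joined by 1 higher over the list alone (median −0.54, adjusted p = 0.140 with an estimated correlation), and loop and proximal tubule markers 3 of 11 lower, or 5 (median −0.26, adjusted p = 0.0739 with an estimated correlation). Oxidative phosphorylation genes had 4 of 17 lower by either adjustment (median −0.17, adjusted p = 0.375 with an estimated correlation). They missed the threshold under each of the 3 other scalings and when any 1 of 7 arrays was left out. Their median was −0.12 after quantile normalization, −0.09 after median centring and −0.04 with cyclic loess. Over their alternatives the adjusted p lay between 0.0123 and 0.390.

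At 24 h 1877 genes differed between the steps. Akr1b1 differed by −1.48, with the same limit near the top of the scale, Nfat5 by −0.57, Slc6a6 by −0.41 and Aqp2 by 1.59. Unfolded protein response genes had 8 of 18 higher, or 10 adjusted over the list alone (median 0.37, adjusted p = 0.00233 with an estimated correlation), and matricellular genes 9 of 12 lower and 1 higher by either adjustment (median −0.82, adjusted p = 0.0252 with an estimated correlation). Passing only at the preset correlation were 5 lists. Proliferation genes had 7 of 23 higher and 2 lower, or 9 and 2 (median 0.33, adjusted p = 0.331 with an estimated correlation). Cytokine genes had 10 of 21 higher and 2 lower, or 11 and 5 (median 0.35, adjusted p = 0.241 with an estimated correlation), and among them Csf2 and Il18 stood at 4.14 and 4.77 in steady 600, near the bottom of the scale. Interferon-stimulated genes had 10 of 19 higher and 2 lower, or 11 and 2 (median 0.72, adjusted p = 0.0885 with an estimated correlation). Glycolysis and hypoxia genes had 5 of 18 higher by either adjustment (median 0.14, adjusted p = 0.153 with an estimated correlation). Tonicity genes had 4 of 10 lower and 1 higher, or 4 and 2 (median −0.19, adjusted p = 0.302 with an estimated correlation). The tonicity list also missed the threshold with cyclic loess (adjusted p = 0.0765) and when any 1 of 6 arrays was left out, the range over its alternatives being 0.0112 to 0.302.

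Among probe sets with no gene listed, which the comparisons did not use, 2614 of 13537 passed the threshold in steady 900 against steady 300, 1412 of them higher and 1202 lower, and 570 changed at least 2-fold.

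Other splits of the same arrays were counted for each number of genes past the threshold. For the 10687 genes that differed among the 10 groups, 1 of 100 splits, the real one, gave as many, the highest other giving 856. This argues against an arbitrary assignment of arrays to groups. It cannot tell the treatment from differences between cultures, since the labels do not say whether replicates were separate cultures. Each comparison of 3 with 3 arrays has 10 splits, so a share under 0.05 cannot be reached, and in each the real split alone, 1 of 10, gave as many. Real numbers lay between 2654 and 6180. The highest other split gave at most 3 genes, except 970 for 12 h against 3 h (real 5939) and 545 for the step from 600 to 900 at 12 h (real 5484). For the differences between the steps, 16 of 100 splits at 12 h and 12 of 100 at 24 h gave as many genes, the highest other giving 5611 against 1947 and 3598 against 1877. Such splits mix arrays of groups that differ from each other, with 5011 and 5484 genes past the threshold for the steps at 12 h. At 24 h these numbers were 3242 and 3763. Those changes can enter the differences of other splits, so this test cannot decide about chance here. By the bound of 0.05 set beforehand, chance was not excluded for either difference.

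The first pattern weighed was that 70.9% of the genes changed at 3 h were lower. A narrower signal range on the 3 h arrays is a candidate explanation, since the share was 20.96% among the dimmest of 3 equal groups of genes by brightness, 70.6% in the middle group and 85.6% among the brightest, and the mean SD over probe sets was 2.28 at 3 h against 2.37 in steady 300. Differences in distribution left after RMA could not be told apart from a change in the cells, since quantile normalization gave 58.34%, between the bounds of 55 and 60 set for it. A real excess of decreases, such as a loss of abundant transcripts under acute osmotic stress, stays open and was not tested.

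The second pattern was the distance of the cells at 48 h from steady 600, with 3185 genes apart. If the cells were slowly approaching the steady profile, the change from 24 to 48 h should run along the change from steady 300 to steady 600. The correlation across genes was 0.1854 (0.166 to 0.204 leaving out any array), between the bounds of 0.1 and 0.2, so a slow approach remains possible and undecided. Culture differences unrelated to osmolality as the whole cause also cannot be told apart, since the difference at 48 h correlated at 0.1843 (0.173 to 0.191) with the change on return from 900 to 300, between the bounds of 0.1 and 0.2.

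The third pattern was that collecting duct genes were higher and cytokine genes lower in steady cultures at higher osmolality. A lower share of non-epithelial cells as the whole cause of the higher collecting duct genes is argued against for steady 900. There the general epithelial markers had a median of 0.33 (0.31 to 0.36 leaving out any marker) against steady 300. The collecting duct genes had 2.01 (1.55 to 2.02). This test and its bounds were set after the result was seen, and the epithelial markers went both ways, 7 higher and 3 lower of 12. They may thus not track the share of epithelial cells, and a shift among epithelial cell types was not tested. Leukocyte number alone setting the cytokine genes is argued against for 48 h and steady 600, since cytokine genes were higher at 48 h than in steady 600 by a median of 1.04 (1.03 to 1.04 leaving out any member) while leukocyte markers had a median of −0.10 (−0.15 to −0.05). Fewer leukocytes as a part of the lower cytokine genes stays open, since at 48 h, with leukocyte markers at −1.03 (−1.22 to −0.83) against steady 300, the cytokine median of −0.03 (−0.12 to 0.07) could combine such a loss with a rise in other cells, which was not tested. An effect of osmolality, the difference the design names, stays open for the steady cultures, and in cells returned from 900 to 300 for 24 h the collecting duct genes fell in 14 and rose in 1 of 19 cases by either adjustment (median −0.78, adjusted p = 5.47e-04 with an estimated correlation).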

How the results depend on the processing

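Cyclic loess normalization was chosen only after the data were seen, and all other alternatives were planned. Of 255 results for named genes 250 passed, and 249 to 251 passed over the settings. The exceptions are Slc6a6, Aqp2 and Nfat5 as described with them. Apart from the genes always named, the rule chose only genes past the threshold in these data. Nearly all of these passes were therefore fixed in advance, and the numbers say little about other genes. No named gene past the threshold turned its direction under these settings. With array weights the numbers of genes past the threshold rose from 3242 to 4994 (24 h after the step from 300 to 600), from 3128 to 5130 (48 h), from 2654 to 4264 (24 h after the step from 600 to 900, against steady 900), from 1947 to 3647 and from 1877 to 3468 (differences of the steps at 12 and 24 h); the cause was not tested. With all probe sets, where more features are tested, they were 17943 in place of 10687 among the 10 groups, 9687 in place of 6041 at 3 h and 7610 in place of 5011 at 12 h. With only the compared arrays in the fit the difference of the steps at 24 h gave 2976 in place of 1877. That setting gave 4470 in place of 6041 at 3 h and 4047 in place of 5939 for 12 h against 3 h. It gave 4307 in place of 5484 at 12 h after the step from 600 to 900. For the difference of the steps at 12 h it gave 1566 in place of 1947. The correlation of changes at 3 h and 48 h was 0.328 in place of 0.279 with cyclic loess. The cause of these was not tested. The number among the 10 groups lay between 9370 and 10685 when all arrays of 1 replicate number were left out. Leaving out each array in turn moved no count of a comparison by over 1.5 times, that of steady 600 against steady 300 lying between 3371 and 3485 and that of the difference of the steps at 12 h between 1614 and 2821, the last without replicate 9 at 12 h after the step from 600 to 900.

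Over all functional list tests, 123 passed at the preset correlation, 53 with an estimated correlation and 204 with fry; for cell type markers the numbers were 45, 20 and 77. An estimated correlation widens the error of a list whose members vary together, and fry does not compare a list with other genes. With fry, 2 lists took the other sign: the collecting duct list at 12 h after the step from 300 to 600 (median 0.06, adjusted p = 0.979 and 0.0252 with fry) and the antioxidant list at 12 h after the step from 600 to 900 (median −0.09, adjusted p = 0.927 and 0.0307 with fry). Of the 168 list calls, 7 were lost with quantile normalization, 2 with median centring, 9 with cyclic loess, 11 with the filter on dim genes, 13 with only the compared arrays and 13 without the arrays numbered 3 and 9, and 15 when some single array was left out. Residuals of 114 same-number pairs correlated at −0.126 to 0.238 (median 0.0118), 11 of them over 0.1, and 12 of 30 arrays correlated best with their own number. Those of 291 other-number pairs correlated at −0.281 to 0.226 (median −0.00837), 20 of them over 0.1. The replicate numbers thus gave no clear pairing of the arrays, but a weak pairing by number is not ruled out. With the replicate number as a block, 5264 genes passed in place of 5473 (return to 300, against steady 900) and 2639 in place of 2654 (24 h after the step from 600 to 900, against steady 900). Signal over background is not given in the sources used here, and the number of arrays limits the precision.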

Other observations

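The genes named here were chosen after their values were seen, and no test in this part was chosen only after the result was seen. The gene groups below were fixed beforehand, and several changed after the step from 600 to 900 mosmol/kg. At 24 h unfolded protein response genes rose in 9 of 18 cases, or 11 adjusted over the list alone (median 0.24, adjusted p = 7.11e-05, and adjusted p = 0.0136 with an estimated correlation). Ddit3, a stress-induced transcription factor, rose by 0.82 ± 0.10, and Trib3, a pseudokinase of the same response, by 0.89 ± 0.13. In steady 600 against steady 300 the list was lower, with 10 of 18 genes lower, or 12 with 1 higher adjusted over the list alone (median −0.23, adjusted p = 0.00151, and adjusted p = 0.0413 with an estimated correlation). Antioxidant genes rose at 24 h in 8 and fell in 2 of 17 cases, or 10 and 2 adjusted over the list alone (median 0.23, adjusted p = 0.00130, and adjusted p = 0.0372 with an estimated correlation), among them the quinone reductase gene Nqo1 (0.81 ± 0.09). Glycolysis and hypoxia genes rose in 6 and fell in 2 of 18 cases, or 7 and 2 adjusted over the list alone (median 0.13, adjusted p = 0.00350, and adjusted p = 0.1001 with an estimated correlation). Oxidative phosphorylation genes fell at 12 h in 13 of 17 cases, or 14 adjusted over the list alone (median −0.35, adjusted p = 8.28e-04, and adjusted p = 0.126 with an estimated correlation).

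Transport genes also moved at 12 h. Ion transport and cell volume genes rose in 8 and fell in 1 of 16 cases by either adjustment at 12 h after the step from 600 to 900 (median 0.22, adjusted p = 0.00213, and adjusted p = 0.126 with an estimated correlation). Slc12a2, the sodium-potassium-chloride cotransporter that raises cell volume, rose by 2.05 ± 0.07, and Stk39, a kinase that activates it, by 0.73 ± 0.08. Amino acid transporters rose in 7 and fell in 2 of 14 cases by either adjustment (median 0.31, adjusted p = 0.00213, and adjusted p = 0.126 with an estimated correlation), among them the cationic amino acid transporter gene Slc7a1 (1.4 ± 0.11) and the glycine transporter gene Slc6a9 (1.04 ± 0.08). After the step from 300 to 600, Slc38a4 rose by 2.19 ± 0.09 at 12 h. The ion transport list passed after that step too, with 6 higher and 3 lower at 12 h over all genes tested (adjusted p = 8.77e-04). At 24 h it had 6 higher and 2 lower (adjusted p = 0.00394), and at 48 h 6 and 2 (adjusted p = 0.00222). With an estimated correlation these 12, 24 and 48 h calls were lost at adjusted p = 0.153, 0.155 and 0.131. General epithelial markers were higher in 7 and lower in 3 of 12 cases in steady 900 against steady 300 by either adjustment (median 0.33, adjusted p = 0.201). Intercalated cell markers passed as a list in none of the 17 comparisons. Their members went both ways in steady 900 against steady 300, with 6 higher and 2 lower of 13 by either adjustment (median 0.28, adjusted p = 0.137). The anion exchanger gene Slc26a4 changed by −3.96 ± 0.14 and the carbonic anhydrase gene Car2 by 2.29 ± 0.10.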
